A study of Mus musculus with 2 samples.

How the data were processed

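The series holds H3K27ac peak lists from 2 biological replicates of mouse neural tube at embryonic day 15.5, a pooled list and a replicated list, all in narrowPeak format on mm10 (GRCm38). Per the deposited listings, the replicated list was made by the authors from the replicates' lists and the pooled list, and the pooled list from both replicates together. Per the labels, the mice were B6NCrl, each replicate was a pool of embryos of both sexes, and the size range was 300 to 500 bp. The score used as signal is column 7, the authors' signal value per peak as deposited; its scale is not given in the sources used here. Columns 8 and 9 hold the -log10 p and -log10 q of each peak as the authors deposited them, and column 10 the distance from the start of the peak to its summit. The peak caller, aligner, thresholds, control and read numbers are not given in the sources used here. No reads were aligned and no peak was called again; 2 text listings were read and hold no measurements. The smallest -log10 p was 2.02 in replicate 1 and 2.14 in the replicated list, and 58.0%, 60.8% and 93.5% of the peaks of replicate 1, replicate 2 and the replicated list had a value of at least 5.

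Gene models were GENCODE M21 on GRCm38, with 21826 protein-coding genes and 54280 protein-coding transcription start sites (TSS). Peaks on the chromosomes were used, 61079 in the replicated list; those on scaffolds are described at the end. An overlap counted from 1 bp. A peak was promoter if it overlapped 1 kb to either side of any protein-coding TSS and distal otherwise, and a gene was marked if a replicated peak overlapped this window of any of its TSS. Where several peaks did, the highest signal was used. Local coverage was the share of bases within 10 kb of the gene's 5' end under peaks. Means and SDs are over the replicates' own lists, n = 2. Those of promoter signal are given only where both replicates had a promoter peak, and those of coverage count a replicate without a peak as 0%. Chance overlap came from 100 random circular shifts of a list within chromosomes.

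Of the 28 gene lists, 27 were written gene by gene before the data were examined, and the olfactory receptor list was set by then as all genes of that family by symbol. Fixed by then were also the 13 motifs, the tests, the alternatives and the rule for naming genes. The lists are neural progenitor and radial glia, dorsoventral progenitor domain transcription factors, floor plate and roof plate, motor neuron, inhibitory spinal interneuron, excitatory spinal interneuron, pan-neuronal, synapse and neurotransmitter receptor, oligodendrocyte lineage, astrocyte, Hox paralogue groups 1 to 5, 6 to 9 and 10 to 13, forebrain and midbrain transcription factors, sensory neuron and neural crest, meninges and mesenchyme, cartilage and bone, skeletal muscle, heart, endothelium, microglia and macrophage, erythroid, liver, epidermis, germ line, cell cycle, housekeeping and olfactory receptors. All genes of the lists were found in the annotation, Drgx as Prrxl1. This synonym was looked up after a first run without it. Named from each list were up to 3 marked members with the highest signal in the replicated list and up to 2 unmarked members that came first in the list. All Hox genes, the genes of the top 10 domains, and the 5 strongest promoter and 5 strongest distal peaks were also named; any other gene was chosen after its values were seen, as the text says.

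Lists were tested at promoters with Fisher's exact test, two-sided, against all other protein-coding genes, and as an alternative against 10000 random lists of the same size matched on the decile of the CpG observed-to-expected ratio within 500 bp of the gene's 5' end. Local coverage was tested as the median of the list against 10000 such random lists. The smallest p these can give before adjustment is 0.0002. The CpG ratio was taken at 1 TSS per gene while marking used every TSS. Domains were made by joining replicated peaks within 10 kb of each other, and ranked by the sum of width times signal. Motifs were matched as consensus on both strands in 500 bp at the summits of distal peaks. Controls lay 5 to 50 kb away outside all pooled peaks, matched on GC content in bins of 2%, and were compared by Fisher's exact test. Adjustment was by Benjamini-Hochberg at 0.05 within each set of tests.

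The tests were tested on simulated data with planted effects. At promoters 38 of 40 planted lists were recovered and 1 of 100 unplanted lists was called; against matched random lists these were 40 of 40 and 1 of 100. Local coverage recovered 20 of 20 and called 3 of 100, and motifs 2 of 2 and 1 of 11 (5000 windows). The planted effects were large, and for local coverage no list was planted lower. Genes were simulated independently and unplanted lists were drawn at random. The simulation therefore does not cover small effects, lower coverage, peaks shared by neighbouring genes or lists alike in CpG ratio. A planted overlap of 50% came back as 50%, and a planted correlation of 0.8 as 0.798 (10000 peaks).

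Alternatives changed 1 choice at a time, except that the matched random lists at promoters changed the genes compared with and the test together: the overlap that counts, a -log10 p of at least 5, equal numbers of top peaks, merging of touching peaks, the promoter and coverage windows, 1 TSS per gene, matching of random lists and controls, the joining distance and ranking of domains, the motif window and its centre, the pooled list, and each replicate's own list. The excitatory interneuron list without Drgx and the ranks of the miR-9 genes were added after the data were seen. With 1 group of 2 replicates no comparison of conditions was possible. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.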

Results

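The data were peak lists from chromatin immunoprecipitation and sequencing of H3K27ac, acetylation of lysine 27 of histone H3, a mark of active promoters and enhancers. The tissue was neural tube, the structure that gives rise to the brain and spinal cord, of B6NCrl mouse embryos at embryonic day 15.5. The sample descriptions name neural tube and do not say which part along its length was taken. There was 1 group with 2 biological replicates, each a pool of both sexes. Replicate 1 came from 78 embryos and replicate 2 from 62. No second tissue, stage or treatment was part of the series, so the comparisons are between the replicates and between parts of the genome. Replicate 1 held 92402 peaks over 46.5 Mb and replicate 2 held 97441 peaks over 51.4 Mb. A list called on both replicates together, the pooled list, held 131967 peaks over 73.6 Mb. The replicated list, which the values below use unless a replicate is named, held 61089 of these over 56.0 Mb. The lists carry no read counts, so the sequencing depth is unknown and an unlisted region means only that no peak was called there. Errors are standard deviations over the replicates, n = 2, and the scale of the signal value is not given in the sources used here.

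The first question was how far the replicates went together. The strongest promoters of the replicated list are given first with their signal in each replicate. They were picked by the values of the pooled list, called on both replicates together. High values in each replicate are therefore largely fixed by that choice and do not measure agreement. Kmt5b, a histone H4 lysine 20 methyltransferase, had a promoter signal of 59.0 in replicate 1 and 54.8 in replicate 2. Arrdc3, an arrestin-domain protein, had 54.1 and 51.9, and Nrf1, a transcription factor of mitochondrial and growth genes, had 49.7 and 48.6. Klf7, a Krüppel-like factor of developing neurons, had 58.3 and 49.0, and Pcbp1, a poly(rC)-binding protein, had 50.4 and 46.7. The Hox clusters, which encode the transcription factors of head-to-tail identity, were covered alike in the replicates, with 53.9% ± 1.08 of HoxB and 70.3% ± 3.6 of HoxA under peaks. Promoters of connective tissue and cartilage genes differed most among the fixed lists. In the meninges and mesenchyme list 25% of promoters carried a peak in replicate 1 and 66.7% in replicate 2, and in the cartilage and bone list 0% and 40%.

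Over all peaks on the chromosomes, 58726 of the 92391 peaks of replicate 1 (63.6%) overlapped a peak of replicate 2, and 56234 of the 97429 peaks of replicate 2 (57.7%) overlapped a peak of replicate 1. The mean of both directions was 60.6%. Their SD of 4.13 is between the directions of a single comparison and is not a spread over replicates. After 100 random shifts of 1 list along the chromosomes the shares were 3.75% and 3.56% on average, and never above 4.37%. The Jaccard index of covered bases was 0.509, against 0.0106 after shifting. Overlap was 100% in the strongest decile of each replicate and fell to 36.4% in the eighth decile of replicate 1 and 31.4% in the ninth of replicate 2, then rose to 42.6% and 36.3% in the weakest. At replicated peaks that overlapped a peak in each replicate, 47681 in number, the signal values had a Spearman correlation of 0.765 and a Pearson correlation of 0.895 on the log2 scale, across peaks, which are not independent replicates. The SD of the log2 ratio was 0.42, and 85.2% of these peaks were within 1.5-fold. Among distal peaks alone the Spearman correlation was 0.545.

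**Figure D1:**
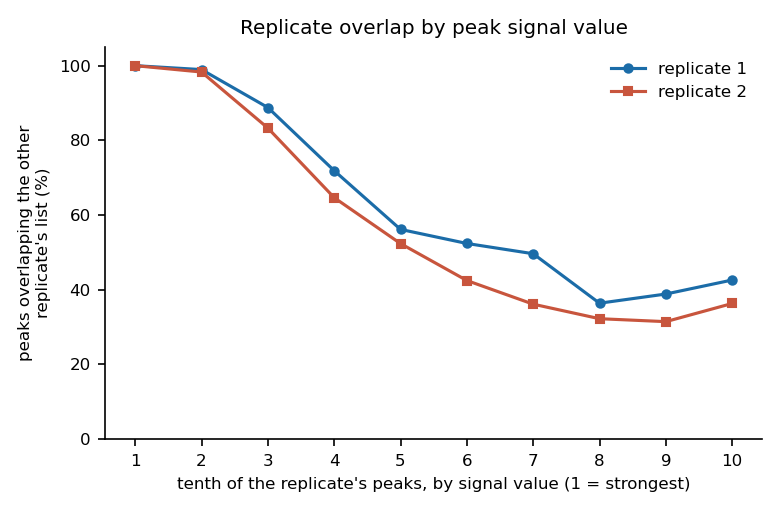
Share of each replicate's peaks (y axis, percent) that overlap a peak of the other replicate, by decile of the replicate's own signal value (x axis, 1 is the strongest). Blue circles stand for replicate 1 and red squares for replicate 2; both fall from 100% in the strongest decile to between 31% and 43% in the weakest 3 deciles.

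The replicated list made up 46.3% of the pooled list, and all 61089 of its peaks stood in the pooled list with the same values. Of its 61079 peaks on chromosomes, 78.1% overlapped a peak in both replicates, 12486 overlapped a peak in only 1 replicate, and 912 overlapped none. The 70875 other pooled peaks had a median signal of 2.50, against 3.76 for the replicated list, and 437 of them overlapped a peak in both replicates. Membership therefore followed a rule other than an overlap of 1 bp with each replicate's list, and that rule is not given in the sources used here.

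The next question was where in the genome the mark lay. Acetylated promoters stood out in number, width and signal: 15908 of the 61079 replicated peaks (26.0%) lay within 1 kb of an annotated protein-coding transcription start site (TSS), against 3.74% after random shifts. Kmt5b (chromosome 19, 3766658 to 3769383, 64.5 in the replicated list), Arrdc3 (chromosome 13, 80882298 to 80887141, 63.3) and Klf7 (chromosome 1, 64117670 to 64123345, 63.2) had the strongest promoter peaks. They were followed by Nrf1 (chromosome 6, 30046506 to 30049530, 55.3) and Pcbp1 (chromosome 6, 86524708 to 86528340, 55.1). Promoter peaks had a median width of 1124 bp and a median signal of 9.30, and distal peaks 540 bp and 3.42. In the replicates' own lists the promoter share was 21.1% ± 0.813, the median promoter signal 6.65 ± 0.146 and the median distal signal 3.2 ± 0.00139. The gap in signal was many times these SDs. They are between 2 medians, each over many peaks, and do not measure the spread of signal among peaks.

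The strongest distal peak, with a signal of 53.9 in the replicated list and 40.8 ± 4.66 in the replicates, lay on chromosome 5 from 115488467 to 115491106 (mm10), 3.742 kb from the nearest protein-coding TSS, that of the mitochondrial sirtuin Sirt4. The 60 bp around its summit, from 115490086 to 115490145, read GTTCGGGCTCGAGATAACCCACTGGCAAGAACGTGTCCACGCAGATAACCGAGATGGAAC. The peak spanned the small nuclear RNA genes Gm24265 and Gm24407. For another pair of strong peaks the nearest protein-coding TSS was that of Chd2, a chromatin remodeller gene, 72.7 kb and 14.9 kb away. One, on chromosome 7 from 73614415 to 73619791, had a signal of 48.4 and the summit sequence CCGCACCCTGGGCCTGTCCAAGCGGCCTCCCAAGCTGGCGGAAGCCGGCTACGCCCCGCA (73618203 to 73618262). The other, from 73556695 to 73559964 with a signal of 45.7, overlapped the 5' end of the noncoding gene 1810026B05Rik. The peak nearest to Scyl1 (chromosome 19, 5799672 to 5805736, 46.0) overlapped the 5' end of Malat1, an abundant nuclear long noncoding RNA. The peak nearest to A830005F24Rik (chromosome 13, 48545341 to 48547399, 44.0) overlapped the 5' end of the noncoding gene 6720427I07Rik. These noncoding genes were named after their values were seen. All 45171 distal peaks were placed by their summit against protein-coding genes alone. Of these, 58.4% lay in introns, 37.9% outside such genes, 1.83% in coding exons and 1.90% in untranslated exons. The peaks outside include those at noncoding genes, such as that at Malat1. The median distance to a protein-coding TSS was 35.6 kb. The promoter share depended on the list used, and was 15.4% in the pooled list.

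Which groups of genes carried the mark at their promoters was asked with 28 gene lists. A promoter is called marked where a replicated peak overlapped the window of 1 kb to either side of any protein-coding TSS of the gene, which held for 12522 of 21826 genes (57.4%). All 16 neural progenitor and radial glia genes were marked, among them Msi1, an RNA-binding protein of neural stem cells (signal 25.8 ± 0.676), the glial switch factor Nfib (22.6 ± 9.04) and the zinc finger factor Zic1 (18.2 ± 0.377). So were all 16 pan-neuronal genes, including the splicing factor Rbfox3, known as NeuN (25.1 ± 8), the adhesion molecule Ncam1 (22.4 ± 5.63) and the neuronal tubulin Tubb3 (20.4 ± 2.20). Of the synapse and receptor genes 13 of 14 were marked, among them the AMPA receptor subunit Gria2 (20.4 ± 1.01), the scaffold Dlg4 (19.4 ± 4.98) and the presynaptic Nrxn1 (20.2 ± 0.603), while the vesicular glutamate transporter Slc17a7, of mainly cortical neurons, was not. All 10 astrocyte genes were marked, with the glutamate transporter Slc1a2 at 17.7 ± 2.66, the glycolytic Aldoc at 7.99 ± 3.64 and the connexin Gja1 at 7.50 ± 0.171. All 12 genes of Hox paralogue groups 6 to 9 and all 15 housekeeping genes, such as Actb (42.0 ± 5.23), Ywhaz (35.4 ± 18.1) and Eef1a1 (32.4 ± 1.55), were marked.

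The lists marked less often than all other genes were those of the forebrain and midbrain, the floor and roof plate, skeletal muscle, heart, liver, blood, microglia, the germ line and olfactory receptors. Only 2 of 18 forebrain and midbrain transcription factors were marked, Neurod6 (7.78 ± 4.40) and Satb2 (3.97 ± 0.319), both known from cortical neurons; Foxg1 and Emx1, which pattern the telencephalon, were not. None of 12 skeletal muscle genes and none of 10 liver genes had a promoter peak, including the myogenic factors Myod1 and Myf5 and the plasma proteins Alb and Afp. The germ line list had 1 of 10, the RNA-binding protein gene Dazl (4.05 ± 0.504), with Ddx4 and Sycp1 unlisted. The microglia and macrophage list had 1 of 10, the purinergic receptor P2ry12 (2.43 ± 0.0479), with the receptors Csf1r and Cx3cr1 unlisted. The erythroid list had 2 of 10, Tal1 (5.03 ± 0.888) and the glycophorin Gypa (3.72 ± 1.3), with Gata1 and Klf1 unlisted. The heart list had 2 of 10, the myosin Myh7 (6.07 ± 0.748) and the natriuretic peptide Nppa (3.45 ± 0.688), with Nppb and Myh6 unlisted. The floor plate and roof plate list had 2 of 10, the signal Shh (7.07 ± 1.82) and the axon guidance cue Ntn1 (5.78 ± 0.489), with Foxa2 and Arx unlisted. Of 1133 olfactory receptor genes 1 was marked, Olfr94 (6.76 ± 0.293).

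The 13 remaining lists were not called. Unlisted here means without a promoter peak in the replicated list. Of the genes named as unlisted, Olig2 had one in each replicate's own list, Slc17a7 in that of replicate 1, and Pax7, Msx1, Avil, Col3a1, Pecam1, Csf1r and Ccnb1 in that of replicate 2. The dorsoventral progenitor list had 5 of 16 marked, among them the proneural factor Ascl1 (10.1 ± 0.687) and the domain factors Irx3 (7.24 ± 0.338) and Nkx6-1 (5.40 ± 0.370), with Pax7 and Msx1, of dorsal progenitors, unlisted. The motor neuron list had 4 of 12, with Foxp1 (37.3 ± 2.60), the receptor Ret (5.25 ± 0.576) and the acetylcholine transporter Slc18a3 (3.48 ± 0.563) marked and the motor neuron factors Isl2 and Mnx1 unlisted. The inhibitory interneuron list had 9 of 12, among them the GABA synthesis enzymes Gad2 (16.5 ± 1.55) and Gad1 (13.6 ± 0.246) and the vesicular GABA transporter Slc32a1 (12.8 ± 0.347), with Ptf1a and Gata2 unlisted. The excitatory interneuron list had 7 of 13, among them the dorsal horn factors Lbx1 (16 ± 2.23) and Maf (16.2 ± 2.67) and the vesicular glutamate transporter Slc17a6 (15.0 ± 1.81), with Phox2a and Evx1 unlisted. The oligodendrocyte list had 6 of 12, with Cnp (6.46 ± 1.31), Pdgfra (5.40 ± 0.370) and Mbp (4.86 ± 0.605) marked and Olig2 and Plp1 unlisted. The sensory neuron and neural crest list had 8 of 14, with the myelin gene Mpz (11.5 ± 1.06), which shares its window with a TSS of Sdhc, Tfap2a (8.37 ± 0.00886) and Pou4f1 (7.83 ± 0.0907) marked and Ntrk1 and Avil unlisted. Hox paralogue groups 1 to 5 had 13 of 15 and groups 10 to 13 had 8 of 12.

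Among the lists of surrounding and general tissue, the meninges and mesenchyme list had 6 of 12 marked, with Foxc1 (5.52 ± 1.07), the pericyte receptor Pdgfrb (4.95 ± 1.09) and Foxc2 marked and the matrix genes Col3a1 and Dcn unlisted. The cartilage and bone list had 3 of 10, Runx2, Hapln1 and Col2a1, with Acan and Matn1 unlisted. These lists had the widest gaps between replicates; smaller gaps in the same direction were found for endothelium (41.7% and 58.3% in replicates 1 and 2), cell cycle (75% and 91.7%), sensory neuron and neural crest (50% and 64.3%) and dorsoventral genes (37.5% and 50%), and gaps the other way for motor neuron (41.7% and 33.3%), synapse (100% and 92.9%) and olfactory receptor genes (0.265% and 0.177%). The endothelium list had 6 of 12, with Kdr (3.59 ± 0.208), Esam (4.75 ± 0.449) and Cldn5 (2.82 ± 0.799) marked and Pecam1 and Cdh5 unlisted. The epidermis list had 3 of 10, Lor (24.7 ± 1.28), Krt10 (23.2 ± 2.03) and Grhl3 (3.75 ± 0.627), with the basal keratins Krt5 and Krt14 unlisted. The cell cycle list had 10 of 12, with the survivin gene Birc5 (29.1 ± 5.61) and the replication factors Mcm2 (6.13 ± 3.2) and Mcm5 (8.25 ± 1.73) marked and Mki67 and Ccnb1 unlisted.

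In Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists, 6 lists were higher and 9 lower than all other genes. The adjusted p was 0.000918 for the neural progenitor, the pan-neuronal and the forebrain and midbrain lists, 0.00119 for housekeeping, 0.0066 for Hox groups 6 to 9, 0.0152 for synapse and 0.0157 for astrocyte genes. It was 0.000502 for skeletal muscle, 0.000922 for liver, 0.00801 for the germ line and the microglia lists and 0.0427 for the erythroid, heart and floor and roof plate lists; that of the olfactory receptors was too small to be stored as a number. Each of these 15 lists lay on the same side of the other genes in both replicates. Genes are not independent replicates, and the promoter CpG ratio went with the mark, from 5.04% of promoters in its lowest decile to 96.4% in its highest. Against random lists matched on that ratio 5 lists were higher and 8 lower: the dorsoventral (adjusted p = 0.00112), motor neuron (adjusted p = 0.0306) and excitatory interneuron (adjusted p = 0.0173) lists were then lower by the permutation test, and Hox groups 6 to 9, heart, microglia, erythroid and liver were no longer called. The astrocyte and heart calls were also lost in each replicate's own list, the cartilage and bone list was lower in replicate 1's own list (0 of 10, Fisher's exact test, adjusted p = 0.000756), and with 1 TSS per gene the synapse, astrocyte, heart, erythroid and floor and roof plate calls ended.

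**Figure D2:**
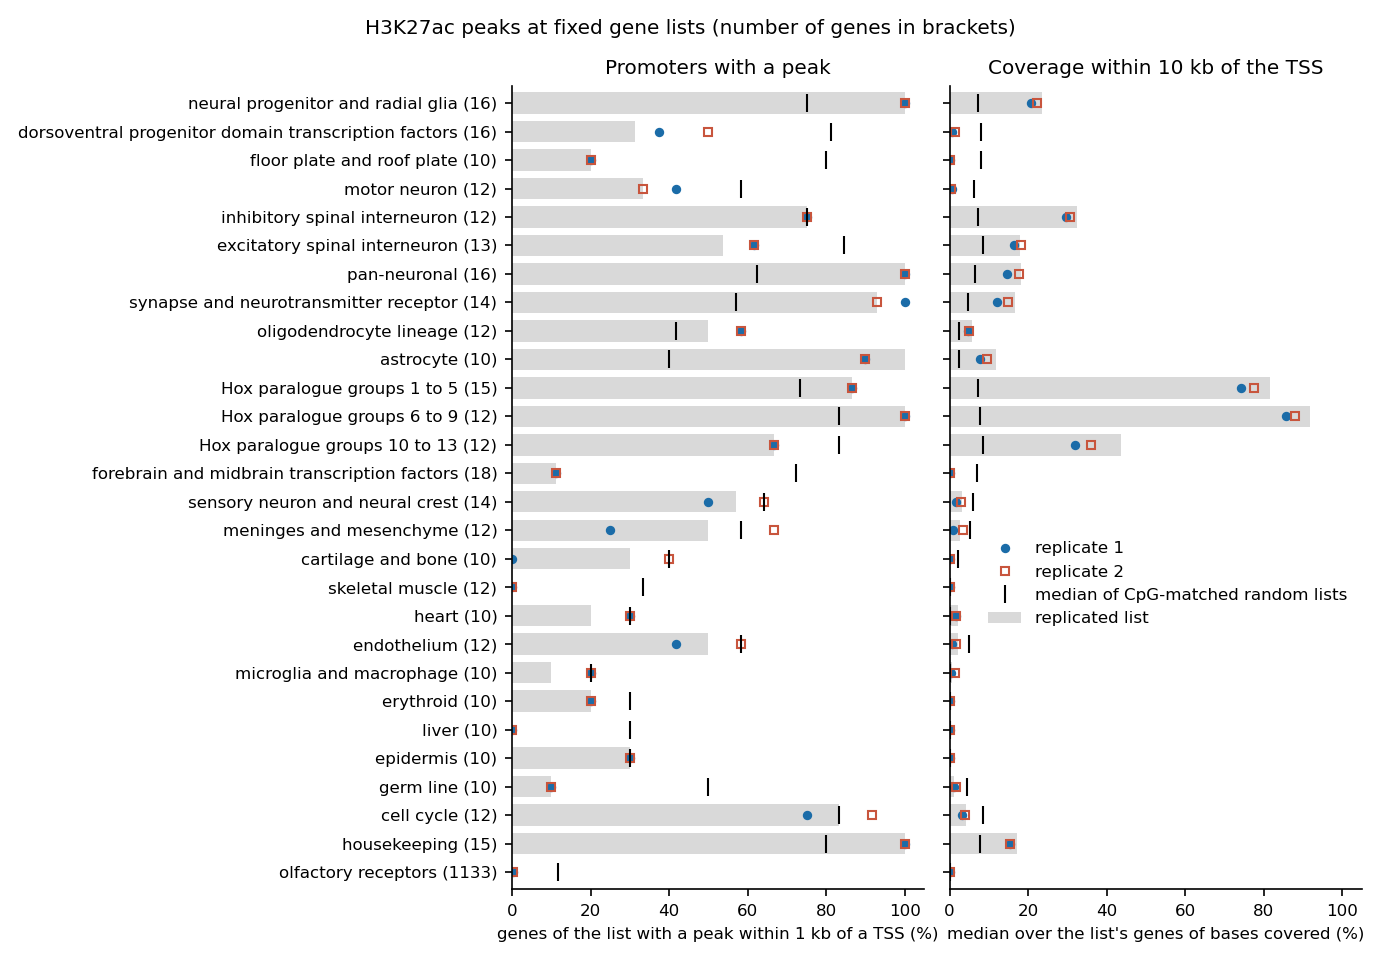
Left, percent of each list's genes with a peak within 1 kb of a TSS; right, the list's median percent of bases within 10 kb of the TSS under peaks. Grey bars show the replicated list, blue circles and red open squares the replicates, and black ticks the median of random lists matched on promoter CpG ratio. The neural progenitor and pan-neuronal lists reach 100% on the left, and the Hox lists reach 43.6% to 91.7% on the right.

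Breadth of the mark around a gene was measured as the share of bases within 10 kb of its 5' end under replicated peaks. Broad acetylation surrounded many genes of inhibitory interneurons and of neural progenitors in general, but few of the factors that set dorsoventral progenitor domains. The median was 32.5% for the inhibitory interneuron list, against 7.11% in random lists of the same size and CpG ratio; Slc32a1 had 52.9% ± 2.86, Gad2 40.2% ± 0.612 and Gad1 19.1% ± 0.276. It was 23.6% against 7.28% for neural progenitor genes, with Zic1 at 71.0% ± 2.95 and Msi1 at 49.2% ± 2.47. It was 18.2% for pan-neuronal, 16.6% for synapse, 11.8% for astrocyte and 17.1% for housekeeping genes, against 6.37%, 4.69%, 2.26% and 7.80%.

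The excitatory interneuron list had a median of 18% against 8.59%, with Lbx1 at 51.8% ± 3.32 and Slc17a6 at 51.6% ± 0.749, while Phox2a and Evx1 had 0%. This call rested on 1 gene. Drgx, a homeobox gene of dorsal horn neurons that the annotation names Prrxl1, was matched through its synonym only after a first run without it, and its own coverage of 18% is the median of the list. Without Drgx the median was 9.98% and the list was not called (permutation test, adjusted p = 0.677). The Hox lists were the broadest, at 81.5% for groups 1 to 5, 91.7% for groups 6 to 9 and 43.6% for groups 10 to 13, against 7.20%, 7.66% and 8.44%.

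The lists with less coverage than matched random lists were the dorsoventral progenitor, floor and roof plate, and forebrain and midbrain lists, each with a median of 0% against 7.92%, 7.96% and 6.95%, and the cell cycle list with 4.07% against 8.57%. Within the dorsoventral list Ascl1 was highest at 24.5% ± 1.27. Pax3, named after its values were seen, had 13.1% ± 0.760, Nkx6-1 9.05% ± 0.0460 and Irx3 8.85% ± 0.488. Pax7 had 1.09% ± 1.55 and Msx1 0.850% ± 1.20. The motor neuron list had a median of 0% against 6.09% and was not called (permutation test, adjusted p = 0.0683). The other lists were not called: the medians were 5.77% for oligodendrocyte, 3.21% for sensory neuron and neural crest, 2.63% for meninges and mesenchyme, 2.17% for heart, 2.06% for endothelium, 1.22% for germ line and 0.570% for microglia genes. The cartilage, skeletal muscle, erythroid, liver, epidermis and olfactory lists had a median of 0%. For all of these but cartilage it was also the median of the matched random lists. A median of 0% cannot lie below a random median of 0%, so the test could not call those lists lower.

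By the two-sided permutation test against 10000 random lists, adjusted over the 28 lists, 10 lists were higher and 4 lower. The adjusted p was 0.00112 for the neural progenitor, inhibitory interneuron and all Hox lists, each from an unadjusted p of 0.0002, the smallest that 10000 random lists can give; it was 0.0014 for pan-neuronal, synapse and dorsoventral, 0.00448 for housekeeping, 0.00436 for forebrain and midbrain, 0.00653 for excitatory interneuron and floor and roof plate, 0.0159 for astrocyte and 0.0204 for cell cycle genes. Hox genes lie in clusters and share peaks and windows, while the random lists were drawn from genes across the genome. The p of the Hox lists therefore cannot be read as one over independent genes. In each replicate's own list all 14 called lists lay on the same side of the random lists. Within 50 kb the excitatory (3.99%) and cell cycle (5.61%) lists lay on the other side of the random lists without being called, and the synapse and astrocyte calls ended. Against random lists not matched on CpG ratio the 4 lower lists and the astrocyte list were not called, and the astrocyte call also ended in replicate 1's own list (7.83%, permutation test, adjusted p = 0.0732).

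The Hox genes were described next because the neural tube spans many axial levels. Of 39 Hox genes, 33 had a marked promoter: 10 of 11 in HoxA, 8 of 10 in HoxB, all 9 in HoxC and 6 of 9 in HoxD. The 6 others were the most posterior genes Hoxa13, Hoxb13, Hoxd12 and Hoxd13 and the anterior genes Hoxb1 and Hoxd1. HoxB carried a single peak of 78.649 kb, the widest of the replicated list, on chromosome 11 from 96268901 to 96347549, with a signal of 34.2 and the TSS of 7 genes, Hoxb3 to Hoxb9. Hoxb3, Hoxb4, Hoxb5 and Hoxb6 were covered in full within 10 kb in both replicates (100% ± 0).

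In HoxA (chromosome 6, 52155590 to 52260880) coverage was 95.6% ± 2.27 at Hoxa3, 95.4% ± 0.728 at Hoxa7 and 86.5% ± 0.0778 at Hoxa9, and went down over Hoxa10 (62.2% ± 5.23) and Hoxa11 (41.5% ± 5.23) to Hoxa13 (0.482% ± 0.682). In HoxC (chromosome 15, 102921103 to 103036852) coverage was 87.3% ± 3.13 at Hoxc9, 68.7% ± 3.78 at Hoxc10, 58.7% ± 1.47 at Hoxc11, 31.0% ± 3.75 at Hoxc12 and 5.35% ± 2.67 at Hoxc13, whose promoter was still marked (4.40 ± 1.55). In HoxD (chromosome 2, 74668310 to 74765142) it was 81.3% ± 0.113 at Hoxd8, 68.5% ± 2.82 at Hoxd10, 36.9% ± 2.27 at Hoxd11 and 27.1% ± 1.53 at Hoxd12, and 0.425% ± 0.601 at Hoxd13. Coverage was also lower at the anterior ends than in the middle of the clusters. It was 48.5% ± 1.87 at Hoxa1, 5.99% ± 2.11 at Hoxb1, 59.8% ± 5.31 at Hoxc4 and 0.872% ± 1.23 at Hoxd1. Over whole clusters, from the first to the last gene, 62.4% ± 3.45 of HoxC and 59.1% ± 2.54 of HoxD lay under peaks. No test was run on the clusters beyond those of the Hox lists above. Neighbouring Hox genes share peaks and windows, and the 5' ends of Hoxd3 and Hoxd4 lie side by side. The annotated 5' end of Hoxa3 (52213336) lies in the same peak as that of Hoxa7 (52221854), and their windows overlap. That of Hoxc5 (102967443) lies beside that of Hoxc10 (102966796). These values are therefore not independent, and the order of the annotated 5' ends is not always that of the paralogue groups. The same number of Hox genes, 33, had a marked promoter in each replicate's own list.

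**Figure D3:**
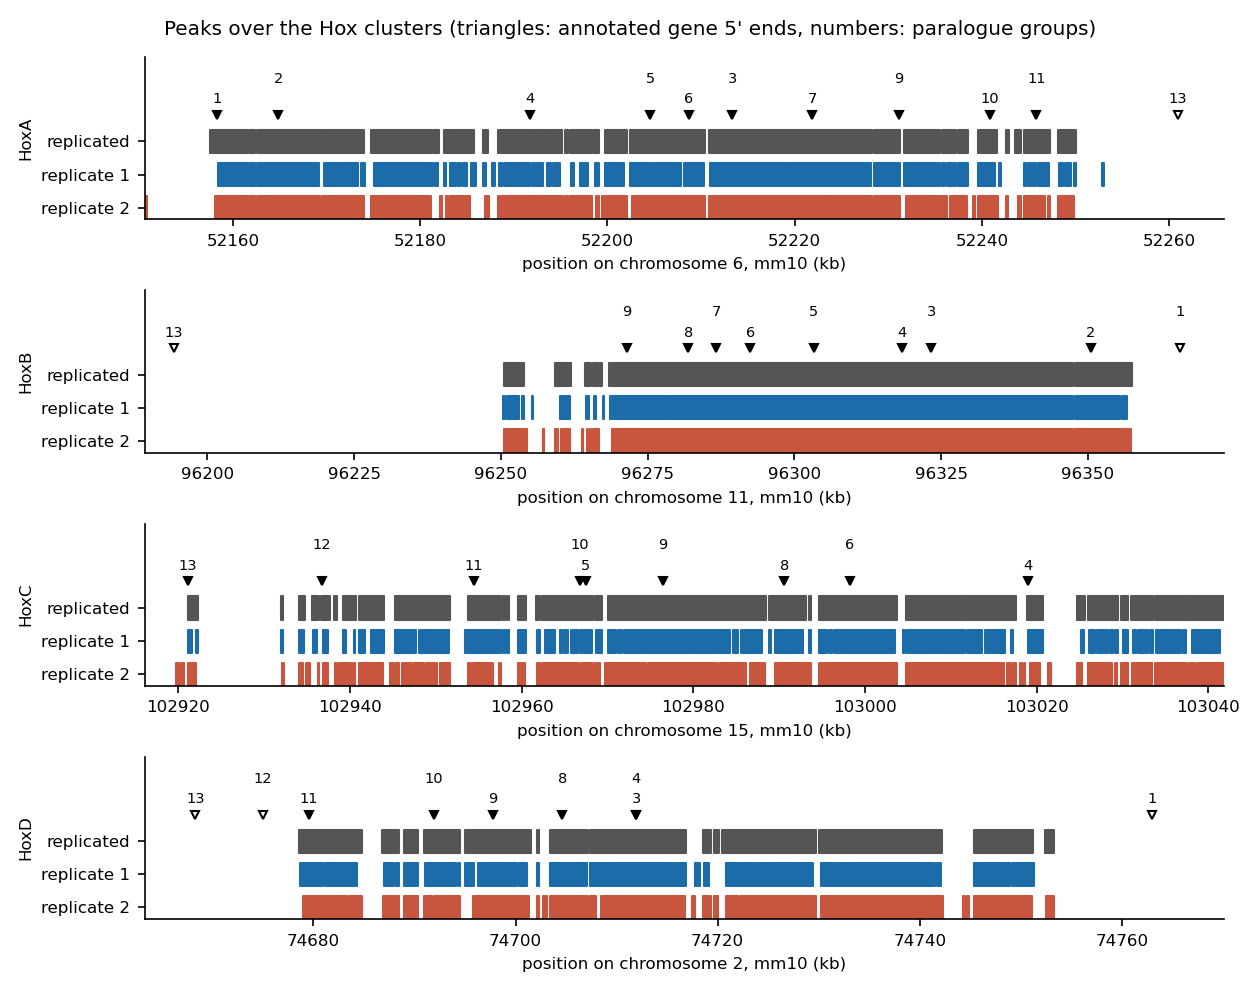
Peaks over the HoxA, HoxB, HoxC and HoxD clusters, with the position on the chromosome in kb (mm10) on the x axis and a row each for the replicated list (grey), replicate 1 (blue) and replicate 2 (red). Triangles mark the annotated 5' ends of the genes with their paralogue group, filled where the promoter carried a replicated peak. One peak of 78.649 kb spans Hoxb3 to Hoxb9, and peaks thin out towards groups 12 and 13 and, in HoxB and HoxD, towards group 1.

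The largest domains of the mark were found by joining replicated peaks within 10 kb of each other and ranking the domains by the sum of width times signal. The 3 highest of 28194 domains were HoxB (chromosome 11, 96250500 to 96357442, 93.7 ± 1.92 kb covered), HoxA (chromosome 6, 52157587 to 52250038, 73.9 ± 3.92 kb) and HoxC (chromosome 15, 102921100 to 103070074, 84.1 ± 5.95 kb), and HoxD ranked 6 (chromosome 2, 74678577 to 74753331, 57.2 ± 2.46 kb). Ebf3, a helix-loop-helix factor of differentiating neurons, held rank 8 (chromosome 7, 137191827 to 137323255, 82.2 ± 5.27 kb).

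The other 5 of the top 10 held no protein-coding TSS. Rank 4 (chromosome 7, 79495712 to 79594297, 58.4 ± 0.0184 kb), nearest to a TSS of the ammonium transporter Rhcg, held the microRNA gene Mir9-3. Rank 9 (chromosome 13, 83712823 to 83761141, 33.5 ± 0.909 kb), nearest to the neuronal factor Mef2c, held Mir9-2, and rank 10 (chromosome 3, 88192505 to 88243858, 44.0 ± 0.631 kb), nearest to Rhbg, held Mir9-1. miR-9 is a microRNA of the developing nervous system, and these are all of its genes in the annotation used. Rank 7 (chromosome 15, 85610307 to 85710357, 48.6 ± 1.44 kb), nearest to the lipid receptor Ppara, held Mirlet7b and Mirlet7c-2, of the let-7 family, and the noncoding gene Lncppara. Rank 5 (chromosome 2, 30628300 to 30726455, 49.4 ± 0.823 kb), nearest to Cstad, held the microRNA gene Mir3089 and the 5' end of the noncoding gene 9330198N18Rik. The noncoding genes were looked up after the ranking was seen. No test applies to the ranking; 11 of the top 20 domains overlapped the top 20 when ranked by covered width, and 10 when peaks within 3 kb of a TSS were left out.

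**Figure D4:**
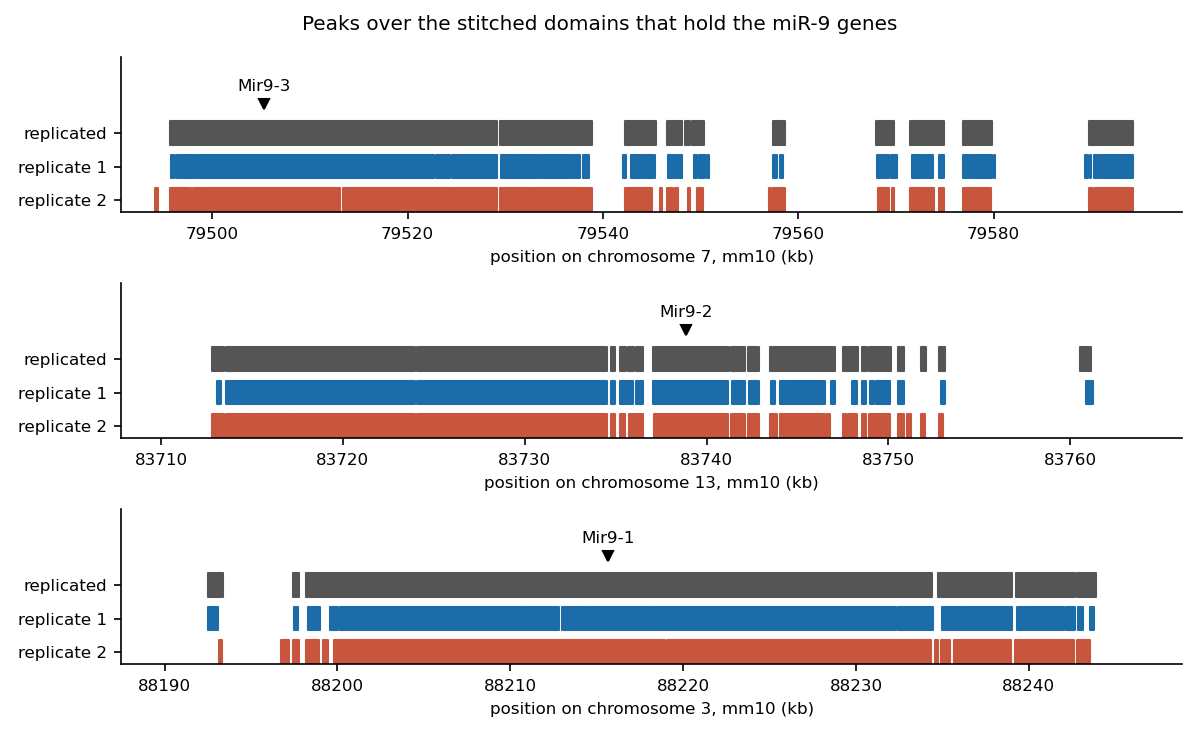
Peaks over the domains that hold Mir9-3, Mir9-2 and Mir9-1, with the position in kb (mm10) on the x axis and a row each for the replicated list (grey), replicate 1 (blue) and replicate 2 (red). Triangles mark the microRNA genes. Within 10 kb of the genes 94.5% ± 1.36, 80.0% ± 2.18 and 98.6% ± 0.636 of bases lay under the replicates' peaks.

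The last question was which sequence motifs the distal peaks held. Sites of RFX factors, which drive cilium and neural tube genes, had the largest odds ratio of the motifs at this window size: 209 of 44733 windows of 500 bp at distal summits held the RFX consensus, against 25 of 44733 control windows of the same GC content (odds ratio 8.39, 95% confidence interval 5.54 to 12.7). The E-box of the proneural factor ASCL1 was in 9.14% of peak and 5.46% of control windows (odds ratio 1.74, 1.65 to 1.83). Sites of MEF2 factors, which act in neurons and muscle, had an odds ratio of 2.04 (1.75 to 2.37), the octamer of POU factors 1.65 (1.52 to 1.79) and the site of LIM and paired homeodomain factors 1.55 (1.44 to 1.66). HOX-PBX sites had 1.22 (1.13 to 1.31), SOX sites 1.20 (1.10 to 1.31), NFI sites 2.00 (1.15 to 3.47, from 38 and 19 windows) and CTCF sites 2.12 (1.79 to 2.51). Sites of AP-1 were rarer in peaks, at 0.944 (0.900 to 0.989).

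Of 13 motifs 10 passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, 9 higher and 1 lower. The adjusted p was 1.28e-36 for RFX, 1.04e-98 for ASCL1, 9.63e-21 for MEF2, 3.52e-34 for POU, 4.68e-33 for LIM and paired, 2.71e-07 for HOX-PBX, 0.00015 for SOX, 5.43e-19 for CTCF and 0.0212 for NFI and AP-1. The NEUROD and NEUROG E-box (odds ratio 1.04, adjusted p = 0.195) and GATA (0.951, adjusted p = 0.195) did not pass Fisher's exact test, GATA being lower in the own lists of replicates 1 (0.942) and 2 (0.901), and the site of the liver factor HNF1 was in 0 windows of either kind. Directions of CTCF and NFI depended on the window: at 200 bp CTCF was rarer in peaks (0.421, Fisher's exact test, adjusted p = 1.42e-06) and NFI stood at 0.889, the NFI call also ended at peak midpoints, and the SOX and AP-1 calls ended at 200 bp. The RFX odds ratio fell to 2.40 at 200 bp (Fisher's exact test, adjusted p = 0.0451) and was 5.64 and 5.28 in the own lists of replicates 1 and 2. Without GC matching HOX-PBX (0.877, Fisher's exact test, adjusted p = 0.000297) and LIM and paired (0.972) lay below 1, MEF2 fell to 1.30 and CTCF rose to 3.30. There the SOX, POU and AP-1 calls ended, and the NEUROD and NEUROG E-box (1.08, Fisher's exact test, adjusted p = 0.00536) and GATA (0.865, adjusted p = 0.000122) were called, higher and lower.

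**Figure D5:**
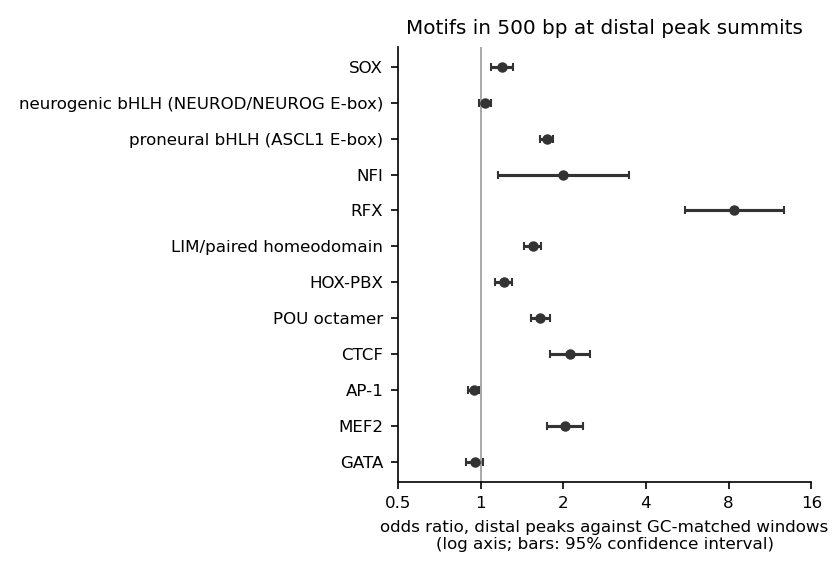
Odds ratio (x axis, log scale) of each motif in 500 bp windows at distal peak summits against control windows matched on GC content. Points are odds ratios and bars their 95% confidence intervals; the grey line marks 1. RFX lies farthest from 1, at 8.39, and HNF1 is left out since no window held it.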

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

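No explanation was tested in this part, and the count below was looked at beside the planned comparisons. The replicated list held 10 peaks on 5 unplaced or unlocalised scaffolds, which the comparisons did not use. They are given because they lie outside the comparisons and number more than the 3 that a count of 0 allows, a limit that any list with scaffold peaks passes easily. They covered 8489 bp, with a median signal of 4.28 and a highest of 40.2. Replicate 1 had 11 such peaks, replicate 2 had 12 and the pooled list 13. Genes on these scaffolds were not examined.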

How the results depend on the processing

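The list without Drgx and the miR-9 ranks were added after the data were seen; all other alternatives were planned. Replicate overlap was 50.7% when at least 0.5 of the peak had to be shared, 66.7% for peaks with a -log10 p of at least 5 and 82.4% for the top 20000 peaks of each replicate. The rank correlation of shared signal was 0.745 with width-weighted signal, 0.825 at a -log10 p of at least 5 and 0.545 at distal peaks. The share of replicated peaks that overlapped both replicates was 58.2% at 0.5 of the peak and 56.1% with only peaks at a -log10 p of at least 5 in all these lists. The promoter share was 24.4% within 500 bp, 31.0% within 3 kb, 21.7% with 1 TSS per gene, 27.4% at a -log10 p of at least 5 and 15.4% in the pooled list; without replicate 1 or 2 it was 20.5% to 21.6%. Of the top 20 domains 11 were shared when ranked by covered width and 10 with peaks over 3 kb from every TSS, and 15 to 20 under the other alternatives. Wider windows and smaller lists change these shares by construction; for the other values the cause was not tested.

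Gene lists called numbered 11 to 17 at promoters (15 in the report), 10 to 14 for local coverage (14) and 7 to 11 for motifs (10). Called under every alternative run were 7 of 15 lists at promoters: neural progenitor, pan-neuronal, forebrain and midbrain, skeletal muscle, germ line, housekeeping and olfactory receptors. For local coverage these were 7 of 14, the neural progenitor, inhibitory interneuron, pan-neuronal, housekeeping and 3 Hox lists, and for motifs 3 of 10, ASCL1, RFX (with an odds ratio of 2.40 at 200 bp) and MEF2 (1.30 with controls not matched on GC). Beside the changes given in the report, the astrocyte promoter call ended within 500 bp, the heart call within 3 kb and in the pooled list, and the microglia call in the pooled list. Gained at promoters were Hox groups 1 to 5 within 500 bp, with 1 TSS per gene and at a -log10 p of at least 5, cartilage and bone at that threshold, and cell cycle in replicate 2's own list. Of these, cartilage and bone was gained as lower and the others as higher. Gained for local coverage were microglia within 50 kb, as higher, and olfactory receptors against unmatched lists, as lower. Direction turned within 50 kb for excitatory interneuron (3.99%) and cell cycle genes (5.61%), at 200 bp for NFI (0.889) and CTCF (0.421), and with controls not matched on GC for LIM and paired (0.972) and HOX-PBX (0.877); the cause was not tested. Without Drgx, 13 lists were called for local coverage, since the excitatory list fell to 9.98%. HNF1 gave no odds ratio under the main setting and was left out. In each setting run, 33 Hox genes had a marked promoter. The depth of the libraries is unknown, and n = 2 leaves the spread between replicates poorly known.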

Other observations

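The tests on microRNA domain length and on unlisted factors, the ranks of miR-9 genes, and all lists and noncoding genes in this part were chosen only after the main results were seen. Long noncoding RNA genes accounted for part of the distal peaks: 1519 of 45171 (3.36%) lay within 1 kb of a long noncoding RNA TSS, against 1.07% after random shifts. These had a median signal of 4.21 and a width of 789 bp, against 3.42 and 534 bp for the other distal peaks. Of 10155 long noncoding RNA genes 2778 (27.4%) had any replicated peak within 1 kb of their 5' end. Unlike the distal counts, this includes promoter peaks of protein-coding genes, so the peak need not belong to the noncoding gene. Hotair lay inside the HoxC domain and Mir9-3hg, the host transcript of Mir9-3, inside the rank 4 domain. MicroRNA genes of the nervous system differed widely. Coverage within 10 kb was 85.8% ± 2.27 at Mir124a-1, 77.9% ± 3.31 at Mir124a-2 and 49.6% ± 2.24 at Mir124a-3, the genes of miR-124, a microRNA of differentiated neurons. Mir132 had 31.8% ± 1.27 and Mir219a-1, of oligodendrocytes, 36.7% ± 1.01, but Mir128-1 had 0.425% ± 0.601, Mir138-1 2.72% ± 1.22 and Mir138-2 0% in both replicates. The muscle microRNA genes Mir206 and Mir208a had 0% in both replicates, and Mir142, of blood cells, 20.0% ± 3.24.

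Promoters were looked at for 5 of the factor families behind the motifs, without a test; of all protein-coding genes 57.4% were marked. Of 8 RFX genes 6 were, Rfx3 (43.1 ± 0.289), Rfx7 (35.6 ± 3.64), Rfx5 (26.1 ± 3.49), Rfx1 (21 ± 7.51), Rfx4 (9.43 ± 1.97) and Rfx2 (3.73 ± 0.293), while Rfx6 and Rfx8 were not. All 4 NFI, all 4 MEF2 and all 4 class 3 POU genes were marked, and none of the 6 GATA genes was.

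All 3 miR-9 genes lay in the top 10 domains. Of the 10, 9 held a microRNA gene of any kind, against 0.706 on average and at most 5 in 10000 random placements of spans of the same lengths. This argued against length alone as the reason that top domains hold microRNA genes. The placements took no account of gene density, and the Hox domains, with microRNA genes of their own, are among those counted. The count therefore says nothing about miR-9 in particular. A first form of this test counted microRNA genes (15 against 0.943 on average, a 95th percentile of 3 and a highest of 120). It left the question open, since 15 was above that percentile but not above the highest. It was replaced after its result was seen, because microRNA clusters set its upper end. The argument against length alone thus rests on the replacement. MicroRNA genes of the nervous system without miR-9 had a median coverage of 28%, against 0% for those of other tissues (11 genes each, permutation p = 0.00594), so broad acetylation at such genes in general may explain part of the pattern; of these 11 the best domain ranks were 21, 25 and 60, so none reached the top 20. Ranked by covered width, 1 of the 3 was in the top 20, and 2 were when peaks within 20 kb were joined. Mir9-1, Mir9-2 and Mir9-3 ranked 17, 15 and 6 in the pooled list and 7, 12 and 6 in replicate 2's own list. Not all were in the top 10 there, but all 3 were under the alternatives not named here.

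Promoters of the mesenchyme and cartilage lists were listed more often in replicate 2, 9 genes in replicate 2 alone and 0 in replicate 1 alone. More peaks called in replicate 2 was argued against as the whole cause, since with 60000 peaks from each replicate the gap was still 7 genes, and 6 with 40000, a number added later. In a second connective tissue and skeleton list of 30 genes, 8 were listed in replicate 2 alone and 1 in replicate 1 alone (Fisher's exact test against all other genes, p = 0.0446), so more connective tissue or skeletal cells in that pool may explain it. This p is close to the threshold and is not adjusted for the other lists looked at, and genes of other lists leaned the same way (in replicate 2 alone and replicate 1 alone, endothelium 4 and 2, dorsoventral 3 and 1, sensory neuron and neural crest 2 and 0, cell cycle 2 and 0) or the other way (motor neuron 0 and 1, synapse 0 and 1, olfactory receptors 1 and 2). Col1a1 coverage was 3.85% and 19.2% and Col2a1 coverage 5.57% and 14.6% in replicates 1 and 2, and Col3a1 had 0% and 1.87%, so 3 of 5 matrix genes looked at were higher in replicate 2, while Col1a2 had 2.03% and 1.54% and Acan 0% in both.

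Many promoters of the domain factor, floor or roof plate and motor neuron lists were unlisted. Whether genes used by few cells fall below the peak threshold cannot be told apart from other explanations: 6 of 27 such genes (22.2%) had a promoter peak in the pooled list, against 0 of 16 unlisted forebrain and midbrain genes (Fisher's exact test, p = 0.0692). The number of genes keeps this open. No biological explanation was tested for these patterns beyond those named, since the series has 1 group.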
